A study of Mus musculus with 2 samples.

How the data were processed

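Trimethylation of lysine 36 of histone H3 (H3K36me3), a mark that the elongating RNA polymerase II machinery leaves over transcribed genes, was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in hearts of mouse embryos at 16.5 days. Per the labels, both libraries came from pooled hearts of male and female B6NCrl embryos, with separate biosample records, and replicate 2 came from 41 embryos. The number of embryos behind replicate 1 was not given in the sources used here. The size range in the labels was 300 to 500 bp for both libraries. The 2 libraries were biological replicates of 1 group, so the design holds no comparison between conditions.

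The starting point was 4 deposited peak lists. Per the deposited notes, 1 list was called on each replicate's own alignments, 1 on the pooled alignments of both, and the fourth is a replicated list derived from both single lists and the pooled list. All 4 are in narrowPeak form on the mm10 build. The notes name 2 further upstream files for replicate 1's list and 1 for replicate 2's list, without their roles. The peak caller, its version, its threshold, the control and the criterion for a replicated peak were not given in the sources used here. Each peak carries the authors' enrichment value, a ratio over background. It also carries the authors' −log10 p-value and, used here in the single-replicate lists, the authors' −log10 q-value. The lowest −log10 p in every list lay close above 2. These peak values are the authors' own and served to rank, filter or describe peaks within a list. The p-values also entered the matching of genes on peak strength in the test of cell makeup. For Ddx42 and Zfp68 the enrichment values of several lists are printed side by side. The lists give no read counts, so sequencing depth is unknown and no counting interval is given. A difference in depth or enrichment between the libraries changes the number and width of peaks, and so every coverage value below.

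Chromosome lengths of the GRCm38 reference were checked against the peak coordinates, and genes, transcripts and biotypes were taken from the GENCODE annotation of that assembly. Peaks on chromosomes 1 to 19, X and Y were used. The counts and widths of whole lists, the ranking by enrichment and the share of pooled peaks in the replicated list took all peaks. A gene body ran from the lowest start to the highest end of its annotation. Coverage is the percent of bases inside at least 1 peak, whatever the peak's height. Peaks have no strand, so where genes overlap their coverage cannot be assigned to 1 of them.

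Replicates were compared by the percent of peaks with at least 50% of their length inside the other list and by the Jaccard percent of covered bases, beside 100 circular shifts of a list along each chromosome. A protein-coding gene was called marked when peaks covered at least 10% of its body in each replicate. Profiles used genes of at least 5 kb in 20 equal bins from start to end, with 10 kb each side in 1 kb bins, and the 3′ to 5′ ratio set the last 10 bins against the first 10. Exon and intron coverage was compared in marked genes with at least 3 exons, on the annotated transcript with the most exonic bases, leaving out its first and last exons. Domains were replicated peaks joined across gaps of at most 1 kb.

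For each of 21 gene lists, the median coverage of its members was placed among 10000 random lists of protein-coding genes matched on gene length decile. A list is described as high where its percentile was at least 97.5 in both replicates and as low where it was at most 2.5 in both. Random medians were often 0, and a tie then keeps a percentile away from the low end, so the rule can rarely call a list low. The percentiles describe these libraries and are not p-values. No p-value is given, and any spread printed is that between these 2 libraries.

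The main tests, gene lists, rule for named genes and most alternatives were fixed before the data were examined. An added setting for 2 ratios and other tests said to be so were chosen later. The 97.5 and 2.5 bounds were set later, before any list result was seen. The named-gene rule took, per list, the 3 members with the highest and the 1 with the lowest mean coverage, with ties going to the longer gene. It also took the 5 protein-coding genes of at least 10 kb with the highest coverage, the 5 of that length with the largest difference between replicates in each direction, the genes under the 10 longest domains and the genes under the 5 replicated peaks with the highest enrichment. Genes named outside that rule were chosen after their values were seen and are said to be so, except 4 X-linked genes chosen for a test before their values were seen.

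The alternatives were stricter peak thresholds (−log10 q of at least 2, −log10 p of at least 5), equal numbers of peaks per replicate, other overlap minimums, each replicate alone, the replicated list in place of the replicates, peaks joined across gaps, other coverage minimums, gene length limits, GC matching, isolated genes and other domain gaps. Computation used Python 3.11.15, NumPy 2.4.6 and pandas 2.3.3. The interval code was tested on simulated peaks. It returned a 3′ to 5′ ratio of 2.97 for a planted ratio of 3 in 200 genes, an exon to intron ratio of 2.01 for a planted 2, and all 200 genes planted at 40% as marked, with 6 of 2000 genes planted at 5% also marked. The overlap counts were checked with bedtools 2.31.1 coverage, which gave the same 72544 and 39883 peaks.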

Results

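H3K36me3 was profiled in 2 libraries of pooled embryonic mouse heart at 16.5 days. Replicate 1 had 185196 peaks with a median width of 327 bp, which covered 86.6 Mb or 3.18% of the placed genome. Replicate 2 had 88540 peaks with a median width of 279 bp, which covered 31.3 Mb or 1.15%. The pooled list held 145156 peaks and the replicated list 114362 peaks with a median width of 412 bp. Sequencing depth is unknown for both libraries, so the lower number in replicate 2 sets the scale of every mean and SD that follows.

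The question of where the mark lay was answered by the annotation under the peaks. Bodies of protein-coding genes held 94.9% ± 0.539 (SD, n = 2) of covered bases and make up 38.2% of the genome. Introns held 74.5% ± 2.00 and exons 20.4% ± 2.54, against genome shares of 35.5% and 2.71%. Coding sequence held 13.3% ± 2.35 and 3′ untranslated regions 7.26% ± 0.259, against 1.31% and 1.19% of the genome. The region within 1 kb of transcription start sites held 0.350% ± 0.00102 of covered bases but is 1.52% of the genome. Sequence outside all annotated genes held 4.27% ± 0.435 and is 55.2% of the genome. In circular shifts of the replicated list, the highest share in gene bodies was 44.3% and the lowest share in the start site windows was 1.48%, and both replicates lay outside those bounds.

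**Figure D1:**
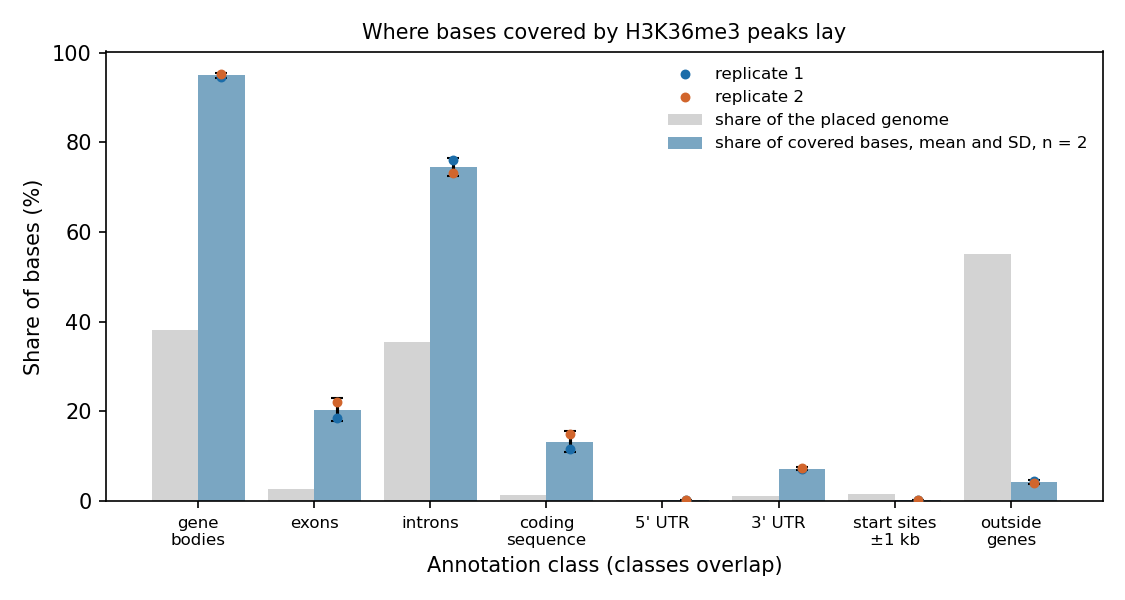
Share of covered bases (blue bars, mean with SD, n = 2; points, each replicate) and share of the placed genome (grey bars), in percent, for annotation classes that overlap each other. Gene bodies hold 94.9% of covered bases and 38.2% of the genome, while sequence outside genes holds 4.27% and 55.2%.

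Along gene bodies, coverage was lowest at the start and rose toward the 3′ end. Over 17798 protein-coding genes of at least 5 kb, the first of 20 bins was covered by 0.924% in replicate 1 and 0.278% in replicate 2. Coverage peaked in bin 19, at 21.0% and 8.51%, and then dropped past the gene end. The last 10 bins were covered 2.19 ± 0.159 (n = 2) times as much as the first 10. By gene length, with bounds at 15.0 and 41.3 kb, this ratio was 2.64 ± 0.272 for the shortest genes, 1.96 ± 0.117 for the middle and 2.07 ± 0.0967 for the longest. Among 3622 marked genes of at least 5 kb it was 2.07 ± 0.203.

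**Figure D2:**
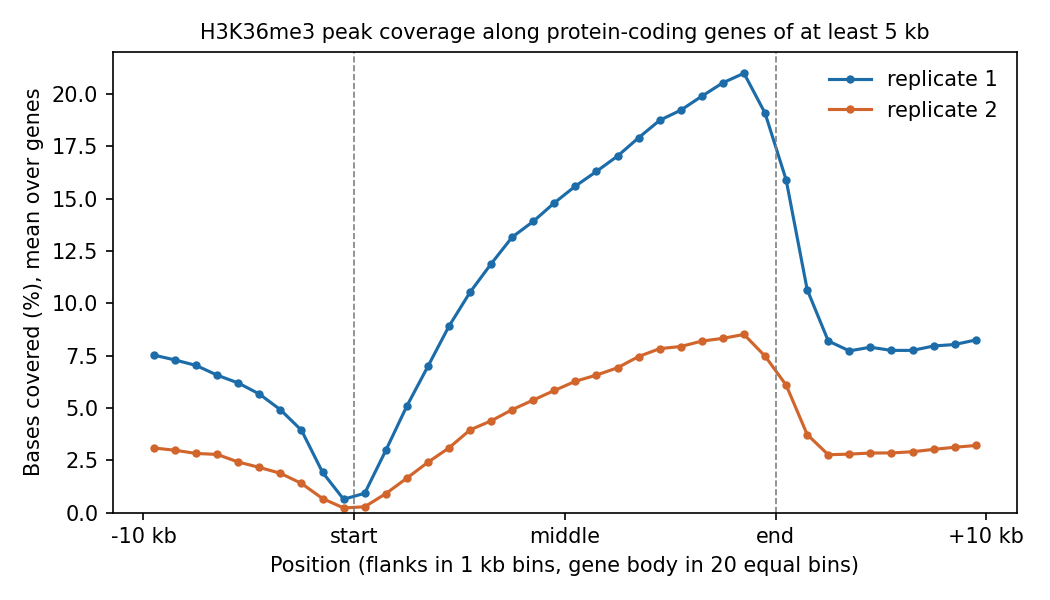
Percent of bases covered by peaks, averaged over 17798 protein-coding genes of at least 5 kb, for each replicate (lines), from 10 kb before the start to 10 kb after the end. Both replicates are lowest at the start and highest in bin 19 of 20, at 21.0% and 8.51%.

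Internal exons were covered more than introns of the same genes. In 3797 marked genes, exons were covered by 72.5% in replicate 1 and 39.3% in replicate 2, and introns by 40.4% and 17.4%. The exon to intron ratio was 2.02 ± 0.327 (n = 2), and it was 1.80 ± 0.274 when exons and introns were compared within the same position bins and 1.82 ± 0.259 within the same gene. Exons had the higher coverage in 84.3% of the genes in replicate 1 and in 76.1% in replicate 2. The ratio exceeded 1 in both replicates under each of these comparisons. With all internal exons set against introns of at most 2 kb only, not matched by gene or position, it was 1.31 ± 0.117.

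Of 21938 protein-coding genes, 3972 (18.1%) were marked in both replicates. Replicate 1 alone marked a further 3661 genes and replicate 2 alone 11, and 10439 genes had no covered base in either. Zinc finger genes led the genes of at least 10 kb. Zfp110 (chromosome 7, 12834761 to 12850577) was covered by 79.98% ± 8.49 (n = 2), Zfp606 by 79.96% ± 2.20 and Zfp68 by 75.5% ± 7.04. Prrc2a followed at 73.8% ± 13.0 and Prpf8, a core spliceosome component, at 71.3% ± 18.1. By length, 8.45% of genes under 5 kb, 23.2% of those of 5 to 20 kb, 22.8% of those of 20 to 100 kb and 4.21% of those over 100 kb were marked. Across genes, which are not independent replicates, coverage in the replicates had a Spearman correlation of 0.917. The count rests on the smaller list, since without replicate 2 it was 7633.

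Genes of the cardiac contractile apparatus stood high among genes of their length. The sarcomere list had a median coverage of 31.9% in replicate 1 and 6.51% in replicate 2, at percentiles 100 and 99.9 of random lists. Of its 26 members, 8 were marked in both replicates and a further 13 in replicate 1 alone, and with peaks of −log10 q of at least 2 only, 2 were marked in both. Ttn, which encodes the giant spring protein titin, was covered over 44.6% ± 24.3 (n = 2) of its 279 kb, Tpm1 (tropomyosin) over 36.5% ± 17.0 and Mybpc3 (cardiac myosin-binding protein C) over 33.4% ± 27.6. Myl7, the atrial myosin light chain gene, is 2.15 kb long and had no covered base in either replicate.

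Genes of mitochondrial energy supply also stood high. In the list of fatty acid oxidation and respiration, 23 of 30 members were marked, and 15 at 25% of the body covered, with medians of 52.0% and 25.2% at percentile 100 in both replicates. Cox4i1 (cytochrome c oxidase) had 62.8% ± 12.9 (n = 2), although all of its body lies inside other annotated genes. Atp5a1 had 62.0% ± 7.17 and Atp5b 61.6% ± 13.1, and both encode subunits of ATP synthase. Cd36, the fatty acid transporter gene, was the lowest member at 3.69% ± 3.08.

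Cardiac transcription factors and ion handling genes did not reach the bound. The transcription factor list had 4 of 23 members marked, a further 8 in replicate 1 alone, and medians of 10.3% and 2.00%, at percentiles 96.2 and 94.0. Gata6 was covered by 35.9% ± 20.1 (n = 2), Mef2d by 33.0% ± 16.3 and Srf by 32.5% ± 22.4, while Isl1, a marker of cardiac progenitors, was at 0 in both replicates. In the list of calcium handling and conduction, 2 of 19 members were marked and a further 7 in replicate 1 alone, with percentiles of 95.1 and 85.3. Atp2a2, which encodes the SERCA2 calcium pump, had 54.4% ± 21.3 and Gja1 (connexin 43) 18.3% ± 4.68, both marked, but only Atp2a2 at 25% of the body covered. Casq2 (calsequestrin) had 19.7% ± 18.0 and was not marked, and Hcn4, the pacemaker channel gene, was at 0.

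None of the 4 lists of other cell types of the heart met the bound. None of 18 endothelial and endocardial genes was marked in both replicates, with medians of 2.82% and 0.104% at percentiles 56.2 and 36.1. Eng was the highest of them at 9.90% ± 10.6 (n = 2), followed by Egfl7, with 49.5% of its body inside other genes, at 6.49% ± 9.17 and Fli1 at 3.88% ± 3.15, and Vwf was at 0. In the list of fibroblast, epicardium and valve genes, 2 of 19 were marked, Sparc at 37.7% ± 14.01 and Fn1 (fibronectin) at 37.1% ± 27.8. Vcan had 16.9% ± 10.5 and Aldh1a2 was at 0, and the list's percentiles were 55.1 and 21.6. Of 10 smooth muscle and pericyte genes, Mcam (39.2% ± 17.5) and Smtn (33.8% ± 19.7) were marked, Tagln had 17.8% ± 12.2 and Myh11 was at 0, with medians of 21.1% and 2.26% at percentiles 91.4 and 66.9. Of 15 blood and macrophage genes, 11 were at 0 and Cd68 was the marked member, at 45.1% ± 42.5 over 1.94 kb. With either stricter peak threshold or at 25% of the body covered, no blood gene was marked. Cx3cr1 had 10.6% ± 6.57, with 53.2% of its annotated body inside other genes, Csf1r had 4.02% ± 2.82 and Adgre1 was at 0. The percentiles of that list were 34.2 and 45.1. Replicate 1 alone marked a further 2 endothelial, 3 fibroblast, epicardium and valve, 4 smooth muscle and 1 blood gene, so these counts rest on the smaller list.

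Lists named for tissues outside the heart had no member marked in both replicates, though it was not checked which of their genes the heart also uses. All 12 liver genes were at 0, among them Hnf4a, Apob and Cyp3a11. Of 18 neuron and neural crest genes 16 were at 0, including Rbfox3, and Slc17a7 was the highest at 1.85% ± 0.232 (n = 2), followed by Syt1 at 0.0262% ± 0.0371. Of 19 skeletal muscle genes 16 were at 0, including Ryr1. Ckm, the muscle creatine kinase gene and the 1 member marked in replicate 1 alone, had 18.0% ± 15.5, Myh8 0.962% ± 1.36 and Cacna1s 0.236% ± 0.333. Of 14 lung epithelium and thymus genes 12 were at 0, including Cdh1, with Sftpb at 0.973% ± 1.38 and Epcam at 0.927% ± 1.31. Percentiles of these lists lay between 18.4 and 41.1, since many random lists also had a median of 0.

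At the 10% minimum, broadly used genes were marked in most cases. The cell cycle list had 18 of 21 members marked and medians of 52.8% and 20.3%, with Rrm1 at 52.8% ± 20.6 (n = 2), Mcm3 at 51.3% ± 33.0, Cdk1 at 46.9% ± 26.2 and E2f1 lowest at 11.9% ± 9.45. Of 24 housekeeping genes 17 were marked, with Gpi1 at 64.9% ± 22.6, the elongation factor gene Eef2 at 61.9% ± 14.5, Vcp at 51.5% ± 21.4 and Eef1a1 lowest at 7.36% ± 7.12. Of 72 ribosomal protein genes 55 were marked, led by Rps3 at 64.9% ± 18.9, Rpl23 at 60.4% ± 22.8 and Rps5 at 60.0% ± 19.8, while Rps21, 1.07 kb long, was at 0. In the list named H3K36 enzymes and readers, which also holds related genes such as Supt6, 14 of 20 members were marked. Within this list the demethylase gene Kdm4a had 59.7% ± 24.6, Supt6 51.5% ± 19.2 and the methyltransferase gene Nsd1 37.3% ± 18.6. Dnmt3b was lowest at 5.37% ± 4.26. Each of these lists lay at or above percentile 99.9 in both replicates. With peaks of −log10 q of at least 2 only, 14 cell cycle, 9 housekeeping, 42 ribosomal protein and 5 H3K36 genes were marked, and at 25% of the body covered 7, 4, 30 and 2.

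Among gene families, Zfp zinc finger genes were marked in 171 of 365 cases, 66 at 25% of the body covered and 241 without replicate 2, with medians of 21.7% and 9.18% at percentile 100 in both replicates. Zfp869 on chromosome 8 had the highest coverage of the list at 92.9% ± 4.17 (n = 2), and Zfp808 was at 0. No base was covered in any of 39 Hox genes, such as Hoxc5, Hoxa3 and Hoxd3, or in any of 68 replication-dependent histone genes, such as Hist1h2be, Hist1h2bc and Hist1h1d. Of 1462 olfactory and vomeronasal receptor genes 1457 were at 0 and none was marked in both replicates. Olfr608 had 6.95% ± 9.83, Olfr1157 1.02% ± 1.45 and Vmn1r181 0.702% ± 0.993, all from replicate 1 alone, and Vmn2r7 was at 0. The Hox, histone and receptor lists lay at percentiles of 49.5 to 50, since random lists of matched length typically also had a median of 0. Their medians therefore could not show whether they were covered less than other genes of their length. Of 25 imprinted genes 4 were marked, 1 under either stricter peak threshold, and a further 5 in replicate 1 alone, with percentiles of 90.6 and 30.9. Nnat had 47.6% ± 22.6, all of it shared with Blcap, whose body contains Nnat. Igf2r had 42.0% ± 19.1, Impact 30.1% ± 26.5 and Dlk1 was at 0.

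**Figure D3:**
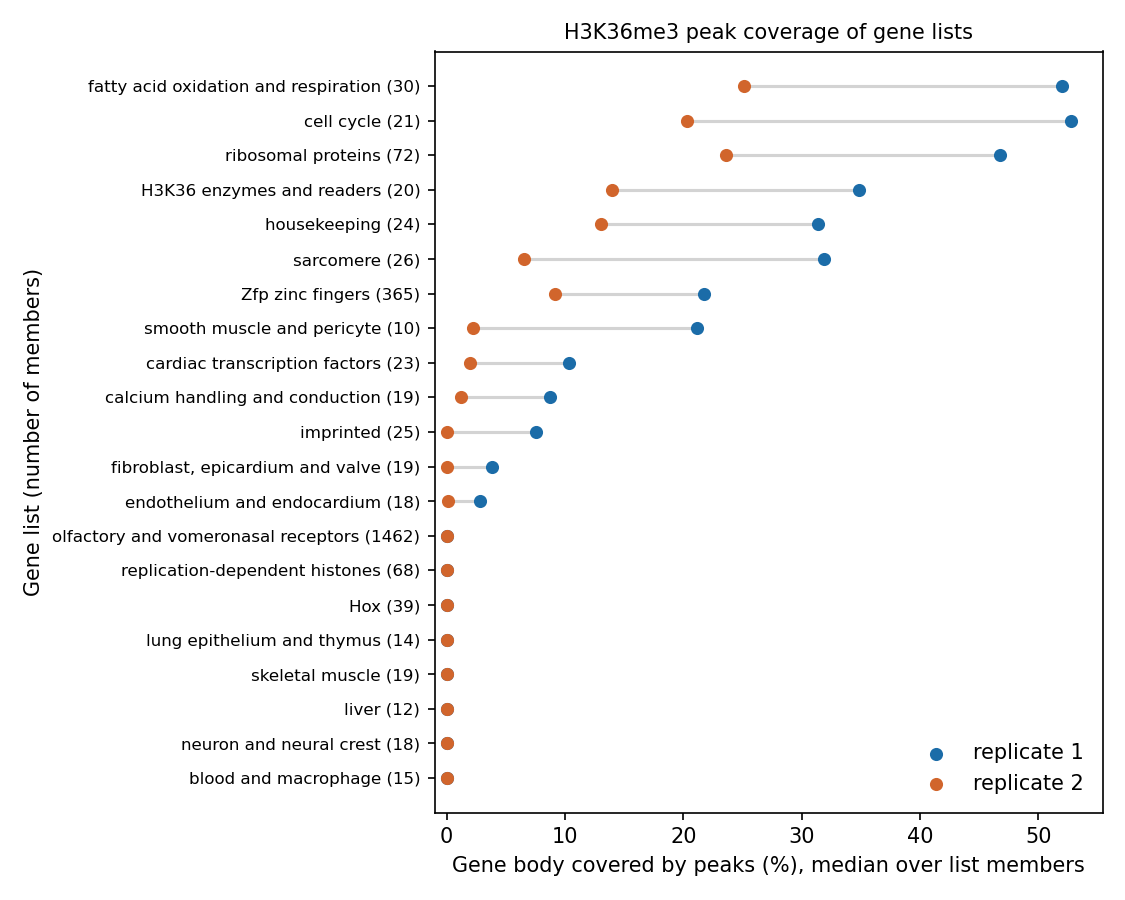
Median percent of gene body covered by peaks for each gene list (number of members in parentheses), with a point for each replicate. Fatty acid oxidation and respiration has the highest mean of both replicates, with medians of 52.0% and 25.2%, and the 8 lists at the bottom have a median of 0 in both replicates.

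Joined across gaps of at most 1 kb, replicated peaks formed 44185 domains with a median width of 862 bp, of which 1279 were at least 10 kb and 176 at least 20 kb. The longest was 60.3 kb wide (chromosome 2, 76702659 to 76762915), with 97.8% of it in Ttn, and peaks of replicate 1 covered 83.2% and peaks of replicate 2 53.6% of it. The next lay in Sptan1 (54.5 kb), Dync1h1 (54.2 kb), Hspg2 (52.1 kb) and Sptbn1 (50.5 kb), which encode spectrin chains, a dynein motor chain and perlecan. Nedd4, Slf2, Ubr2, Hectd4 and Cnot1 held domains of 48.5 to 40.4 kb. Of the domains of at least 10 kb, 99.8% had 50% or more of their width inside protein-coding gene bodies, of 1 gene or more. The count depends on the gap allowed, with 4 domains of at least 10 kb when no gap was bridged.

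Of the 5 replicated peaks with the highest enrichment, 4 lay in zinc finger genes. A peak in Zfp68 (chromosome 5, 138605052 to 138607925) had the authors' enrichment value of 22.3 and lay 96.4% in exons, with 55.0% in coding sequence and 41.4% in 3′ untranslated sequence. Zfp329 (chromosome 7, 12809242 to 12811680) had 18.3 with 99.4% in exons and Ddx42, an RNA helicase gene on chromosome 11, had 17.4. Zfp26 had 17.2 and an additional Zfp68 peak, 87.2% intronic, 17.1.

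Gene bodies on the X chromosome were covered less than those on autosomes. X-linked coverage was 1.90% in replicate 1 and 0.519% in replicate 2, against 8.17% and 2.99% on autosomes, a ratio of 0.203 ± 0.0414 (n = 2). Of 948 X-linked protein-coding genes 27 (2.85%) were marked, against 3945 of 20807 autosomal genes (18.96%). No Y-linked gene was marked. Chromosome 11 had the highest gene-body coverage, 11.1% and 4.10%. The ratio lay below 1 in both replicates, and the pools held male and female embryos.

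**Figure D4:**
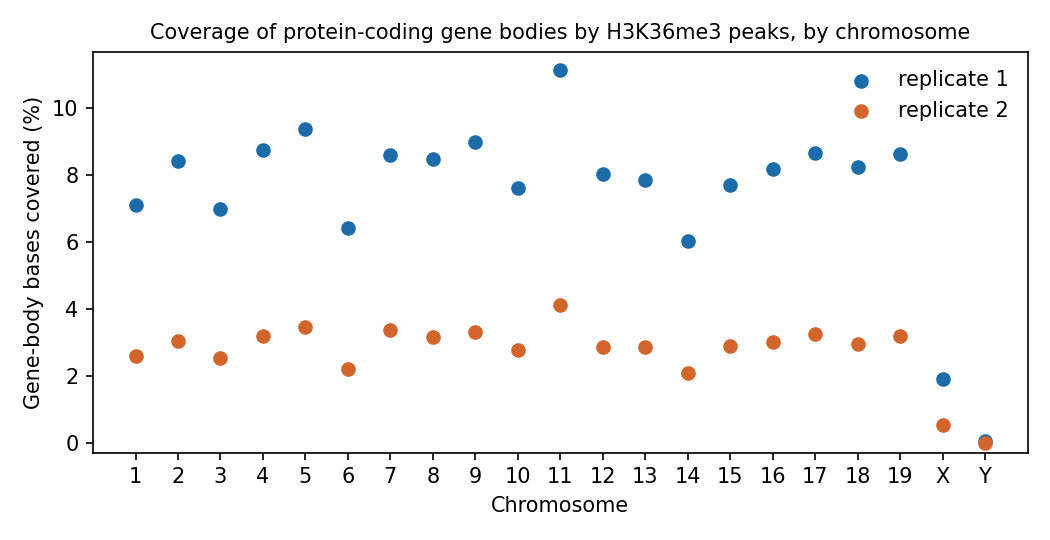
Percent of protein-coding gene-body bases covered by peaks on each chromosome, with a point for each replicate. Chromosome X has 1.90% and 0.519%, and chromosome 11 has 11.1% and 4.10%.

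How far the replicates shared their peaks depended on the list asked. In replicate 1, 81.9% of the peaks of replicate 2 were found at 50% of their length, against 4.79% in the highest of 100 circular shifts. In replicate 2, 21.5% of the peaks of replicate 1 were found, against 1.56%. The lists shared 25.7 Mb, a Jaccard percent of 27.9%. Among the strongest 20% of peaks by −log10 p, 95.02% of those of replicate 2 and 45.9% of those of replicate 1 were found, and among the weakest 20% the values were 70.9% and 8.84%. Among genes of at least 10 kb, Pofut2 had the largest difference, 76.1% in replicate 1 and 23.3% in replicate 2, followed by Nup88, Dnttip2, Sin3b and Ctsd, with 55.7% of Ctsd inside another gene. In the other direction the largest differences among genes of that length were those of Gm35315 at 0 and 3.62%, Nudt2 at 0 and 2.74%, Arhgap45 at 0 and 2.56%, Klf9 at 0 and 2.20% and Ccn6 at 0 and 2.06%.

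The replicated list held 78.8% of the pooled peaks, all with identical coordinates. It held 99.5% of the strongest 20% of pooled peaks by −log10 p and 46.8% of the weakest. Pooled peaks in the replicated list had a median width of 412 bp and those outside it 225 bp. Of the replicated peaks, 38.9% lay at least 50% inside peaks of both replicates as listed, 42.8% had no base in the list of replicate 2 and 3.51% had none in that of replicate 1.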

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

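The tests of cell makeup and of gene content on the X were chosen only after the values they bear on were seen. The bound for ruling out cell makeup was narrowed from the central 95% to the central 50% after its percentiles were seen, which left open what the first bound would have ruled out. Earlier forms of the gene content test, on lists and families that stood high, and a comparison of the both-copy genes with such families were dropped after their values were seen, because choosing by coverage bears on the outcome. On scaffolds outside chromosomes 1 to 19, X and Y, the replicated list held 9 peaks. These entered only the peak counts and widths, the ranking by enrichment and the comparison of the pooled with the replicated list.

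Replicate 2 had fewer and narrower peaks than replicate 1. Of 118117 replicate 1 peaks with no base in replicate 2, 88.9% lay in protein-coding genes that held replicate 2 peaks, against 23.4% in the highest of 100 shifts, and among those in some protein-coding gene body the values were 95.8% and 57.3%. That excess is what a weaker signal over the peak threshold in replicate 2 would give, but pools of different cell makeup that share most transcribed genes would give it too, so the explanations cannot be told apart here, and the lists give no depth or control. The replicate 2 to replicate 1 coverage ratio was set among lists matched on replicate 1 coverage and peak strength. None of 6 cell type lists lay outside the central 95%, the bound first set for ruling out cell makeup. Sarcomere was at percentile 3.71, smooth muscle and pericyte at 5.39, and cardiac transcription factors at 6.52. Fibroblast, epicardium and valve was at 29.4 and calcium handling and conduction at 35.8. Fatty acid oxidation and respiration was at 95.5, but many of its genes are not particular to cardiomyocytes, so its side does not bear on cell makeup. Of 6 lists that name no cell type, ribosomal proteins (99.97) and Zfp (100) lay outside the central 95%, while imprinted genes (95.7), housekeeping (53.1), H3K36 enzymes and readers (46.7) and cell cycle (35.0) lay inside it.

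X-linked genes had low coverage, 0.203 ± 0.0414 (n = 2) of that on autosomes. The tables argue against repeats as the whole cause, since the ratio in unmasked bases was 0.223 ± 0.0472. In the ribosomal protein and housekeeping lists, the 6 X-linked members had 0.316 ± 0.0710 of the median of the 90 autosomal members. They lay at percentiles 0.06 and 3.01 of random autosomal members of the same lists, which were not matched on gene length. Gene content and 1 transcribed X copy per cell therefore cannot be told apart here. A candidate explanation is that each cell transcribes 1 X copy, since Kdm5c (40.1% ± 15.6), Eif2s3x (31.2% ± 13.3), Ddx3x (25.4% ± 8.90) and Kdm6a (3.32% ± 2.09), known to be expressed from both X copies, lay together at percentile 100 of X-linked lists matched on length. This remains a hypothesis, since Kdm6a was low and those lists were not matched on expression level, which was not measured.

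Exons had higher coverage than introns of the same genes. The ratio of 2.02 ± 0.327 (n = 2) was 1.88 ± 0.279 in unmasked bases, which argues against masked repeats as the whole cause. Within 5 classes of local GC content it was 1.95 ± 0.287. GC content was read from the 500 bp window at the middle of each piece of exon or intron. That window need not stand for a long piece, so GC content as a cause is not excluded. With all internal exons set against introns of at most 2 kb, the ratio was 1.31 ± 0.117. Long introns with little signal may account for part of the difference. How large a part cannot be told, since these introns were not matched to the exons by gene or position. Nucleosome density and transcript choice were not tested, and the design names no biological contrast for this pattern.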

How the results depend on the processing

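The equal-number setting for the 3′ to 5′ and exon to intron ratios was chosen only after seeing the data. No paired analysis was possible because there was 1 group. No ratio or list call reversed in direction, and the other values were not scored for reversal. All 21 lists kept their call in all 189 alternative percentiles. With a replicate left out, a high list keeps its call by construction, since a high call needs the bound met in both replicates. In the other settings the 7 high lists could have lost theirs, but a low call was rarely possible. Of 210 alternative counts of marked list members, 158 lay within 1.5 times the main count. Of the other 85 alternative values, 58 did not move beyond a tolerance that differed by result. For shares and ratios it was the spread between replicates, and for counts 1.5 times. For percents of peaks found in another list it was a binomial interval over peaks, which takes peaks as independent. The Jaccard percent had no tolerance, so each alternative of it counted as moved by construction. With 2 replicates, leaving out 1 moves a mean by less than 1 SD whatever the values, so such agreement shows no stability. Causes were not tested unless named.

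Peaks of replicate 2 found in replicate 1 were 88.0% with −log10 q of at least 2, 83.0% with −log10 p of at least 5, 65.3% with equal numbers, 88.7% at 1 bp of overlap and 68.4% at 80%. Peaks of replicate 1 found in replicate 2 were 12.4%, 14.4%, 32.5%, 36.2% and 7.59% in that order, and the Jaccard percent was 18.7%, 19.8% and 32.9% for the first 3. Marked genes numbered 2222 and 2008 under the stricter thresholds, 1073 at 25% coverage, 6456 with the replicated list, and 3983 to 7633 with a replicate left out, as fewer or more peaks give by construction. Start site windows held 0.341% with −log10 p of at least 5, 0.346% with equal numbers and 0.325% with joined peaks, beyond an SD that is small by the near equality of 2 values. The 3′ to 5′ ratio was 1.96 in genes of at least 20 kb. The exon to intron ratio was 2.43 with the replicated list, 2.25 with replicate 2 alone and 2.34 with replicate 1 alone. In these settings 6456, 3983 and 7633 genes counted as marked, so the genes compared changed too. In the 3797 genes of the main result, the ratio was 2.00 with the replicated list, 2.26 in replicate 2 and 1.79 in replicate 1. Domains numbered 23877 across gaps of up to 3 kb and 114353 with no gap, and those of at least 10 kb 3802 and 4. Depth is unknown, so coverage of 0 means only that no peak was called, and signal under the caller's threshold is not excluded.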

Other observations

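The tests in this part were all chosen after the data were seen, and genes and families named here fall outside the rule for named genes. Protein-coding genes were grouped by the letters before the first digit of their symbol, which gave 102 families of at least 20 members. Ddx genes, which encode RNA helicases, were marked in 26 of 37 cases (70.3%), Eif genes of translation initiation in 37 of 55 (67.3%), Gtf genes of general transcription factors in 15 of 23 (65.2%) and Nup genes of the nuclear pore in 13 of 21 (61.9%). In 28 families the median coverage met the bound for a high list in both replicates, against 2000 random lists matched on length. Another 28 families had no marked member, among them Col (collagens, 45 genes), Krt (keratins, 53), Cdh (23), Mmp (22) and Pcdhb (22).

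Sequence outside genes was covered mostly just past gene ends. Sequence that lay within 10 kb both downstream of a gene end and upstream of a gene start was left out of both regions. The rest of the 10 kb downstream of protein-coding genes, outside any gene, held 69.8% ± 1.88 (n = 2) of the covered bases outside genes. It made up 6.17% of the sequence there. The rest of the 10 kb upstream of starts held 1.85% ± 0.373 of the covered bases and 6.76% of the sequence. Of other gene classes, 254 of 2959 antisense genes (8.58%), 68 of 5854 lincRNA genes (1.16%) and 100 of 9940 processed pseudogenes (1.01%) were marked, where overlap with protein-coding genes was not separated.

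In 171 marked Zfp genes the last exon was covered by 68.1% in replicate 1 and 49.4% in replicate 2, and in 855 marked genes of matched length by 56.3% and 29.1%. The 3′ to 5′ ratio was 2.58 ± 0.536 (n = 2) in the Zfp genes and 2.13 ± 0.197 in the matched genes. That difference is within the spread of the first value, but the ratios were not compared within each replicate. The Ddx42 peak, at 17.4 in the pooled list, had 8.23 and 11.2 as the highest overlapping values of the replicates' own lists, while the strongest Zfp68 peak had 22.3, 23.3 and 17.5.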
